A study of Homo sapiens with 6 samples.

How the data were processed

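Total RNA of 6 samples, 3 of A549 cells in 2D culture and 3 of subcutaneous A549 xenograft tumors, was labelled with biotin and hybridised to Affymetrix whole-transcript arrays with human probes, per the labels' protocols. The groups and replicate numbers were taken from the sample titles and descriptions. The deposited intensity values come from 1 table with 53617 probe sets and 1 column per array. They were made with Affymetrix Expression Console and RMA (background correction, normalization between arrays and summary of probes), per the submitters' processing notes; the versions are not given in the sources used here. RMA as usually run gives log2 values, but these intensities are linear: none lies below 1, the array medians lie between 12.7 and 14.6, and the highest value is 10454. The planned test assumed log2 values and allowed for linear ones, so log2 was taken after setting values under 1 to 1, which concerned 0 values. Quantiles were not equal between the arrays and differed by group. The 99th percentile lay between 1251 and 1311 in 2D culture and between 1098 and 1134 in tumor, while the medians were higher in tumor. No further scaling was applied for the main results. The table holds no detection call per probe set, so a gene below the median of an array is described as dim and not as absent. RMA makes the bulk of each array largely alike, so a general shift of RNA content between the groups cannot be seen in these values.

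Probe sets were named through the platform annotation, with symbols updated by gene identifier to those of a RefSeq table of assembly GRCh38.p14, used for names and biotypes only. Of the probe sets, 16098 had 1 gene symbol, 0 had several and 37519 were unnamed here. Where a gene had more than 1 probe set (779 genes), the probe set with the highest mean over the 6 arrays stood for it, which gave 14884 genes, 11916 of them protein coding. No coordinates are given, because the sources used here name no genome build. Of the genes fixed for naming, CA9, CDH1, COL1A1, PTPRC and ACTB were not analysed here, since no probe set carried their names.

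Tumor was compared with 2D culture in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05). Differences are log2 tumor minus 2D culture with the moderated standard error, and group levels are mean intensities. The median standard error was 0.14 and the prior had 6.04 degrees of freedom. Before the data were examined, 31 gene lists were fixed with 555 members, of which 315 had a named probe set. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. Named genes follow a rule of the same date: the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, leaving out most small RNAs, unnamed loci and pseudogenes; in each list up to 4 members with the largest change past the threshold, or the largest difference where none passed; and MKI67, CA9, VEGFA, CDH1, VIM, COL1A1, PECAM1, PTPRC, GAPDH and ACTB. Of the list members the text gives some, and passes over those whose call was lost when an array was left out; LOX and TP53INP1, chosen after their values were seen as the members that went against their lists, are given with their lost calls. Lists of hepatocyte, acute phase, ERK output, lysosomal and histone genes were added after the leading genes, but not the values of these lists, had been seen.

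The fit was tested on simulated data with the real genes' mean levels, 200 changed genes per run and 5 runs over 14884 genes. The real spreads were shuffled among genes and the noise was independent between genes. The fit recovered 16.4% of changes of 0.5 on the log2 scale, 72.5% of changes of 1 and 98.2% of changes of 2. Of its calls, 4.31% were false. Far more genes were called in the real data than were changed here. Of simulated lists, 5 of 5 changed ones and 0 unchanged ones were called. The changed lists held only raised genes, so this does not show how camera behaves with correlated genes. The alternatives were a replicate block, each array left out in turn, median centring, quantile normalization, centring on the list of reference genes, filters on mean log2 intensity at 5 and 6, a trended robust prior, array weights, the mean of a gene's probe sets, a threshold of 0.01, and for lists an estimated correlation, fry, ranks, members of 1 list only and bright members only. Centring on the reference genes adds 0.82 to every log2 difference. A difference or median that turns above 0 with it thus shows only a fall smaller than 0.82. Cyclic loess normalization and protein-coding genes only were added after seeing the data. Lists were also set against 10000 random lists matched on mean expression in 50 classes, which was chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.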

Results

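A549, an established cell line derived from a human lung adenocarcinoma, was profiled under 2 growth conditions. The 2D culture samples are cells grown flat in medium with 10% serum. The xenograft tumor samples come from tumors that formed under the skin of nude mice, an immunodeficient strain without a thymus. For these, cells in 100 µL were injected into male mice 7 to 8 weeks old, tumors were seen within 21 days, and surrounding fat and connective tissue was cut away. Each group had 3 arrays, made from 100 ng of total RNA each, and the number of arrays limits the precision. The labels do not tell whether the arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical. Median probe set intensities lay between 12.7 and 12.8 in 2D culture and between 14.4 and 14.6 in tumor. The array carries human probes, and any mouse RNA in the tumors can be read only through cross-hybridisation.

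Across 14884 genes, Pearson r between arrays was 0.991 to 0.992 within 2D culture, 0.982 to 0.985 within tumor and 0.923 to 0.942 between the groups. These are correlations across genes, which are not independent replicates. The first principal component carried 81.5% of the variance and separated the groups, and the second carried 6.25%.

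The comparison asks which transcripts differ between A549 cells in flat culture and in a tumor grown in mice. The genes of the 3 fibrinogen chains rose most in tumor. FGB rose by a log2 difference of 5.82 ± 0.28 (SE, n = 3 arrays per group; mean intensity 22.9 in 2D culture and 1331 in tumor), FGG by 5.21 ± 0.35 and FGA by 4.68 ± 0.39. Genes of cell division fell together, with all 16 measured mitotic genes and all 17 measured DNA replication genes lower in tumor. GDF15, a secreted stress factor of the TGF-beta family, had the largest fall, by 4.19 ± 0.20, from an intensity of 643 to 35.5. Genes of cholesterol synthesis and uptake also fell, 11 of 11 measured, among them DHCR7, the enzyme of a last step of the pathway, by 2.80 ± 0.18.

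**Figure D1:**
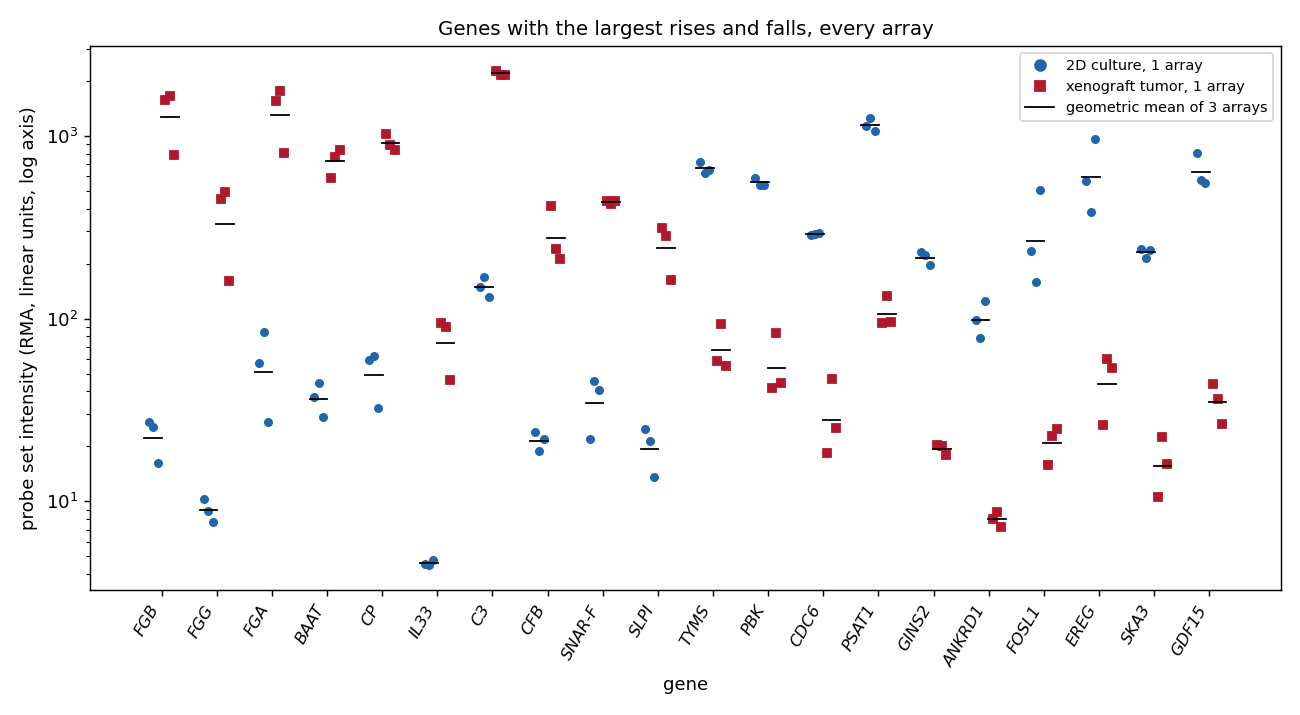
Probe set intensity on a log axis in each of the 6 arrays for the 10 genes with the largest rises (left) and the 10 with the largest falls (right). Circles are 2D culture arrays, squares are tumor arrays and bars are geometric means of 3 arrays; for each gene the 3 tumor values lie on 1 side of the 3 values of 2D culture, with a log2 difference of 5.82 between the bars of FGB.

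Complement and coagulation genes were the list with the highest median. Of 11 measured members of 20, 10 rose and 1 did not pass, also when adjusted over the list alone, with a median log2 difference of 2.84. In camera the list stood above the other genes (adjusted p = 1.91e-08), and the call was lost at adjusted p = 0.244 with an estimated correlation. That setting called no list here, so calls lost there do not tell lists apart. C3, the central component of complement, rose by 3.88 ± 0.13, from an intensity of 150 to 2195 (limma adjusted p = 4.80e-07). CFB, the factor B of the alternative pathway, rose by 3.68 ± 0.23. FGG had a 2D culture intensity of 8.98, below the array median, so its ratio rests on a dim baseline. The other genes with the 10 largest rises lay outside that list. CP, the copper-carrying ferroxidase ceruloplasmin, rose by 4.22 ± 0.23, and SLPI, a secreted protease inhibitor of mucosal surfaces, by 3.65 ± 0.27. BAAT, which conjugates bile acids to amino acids, rose by 4.32 ± 0.18, from 36.8 to 733. IL33, a nuclear alarmin cytokine, rose by 3.996 ± 0.24 from a dim 4.60 to 76.9, and the small noncoding RNA SNAR-F by 3.66 ± 0.23. Markers of host cells were also higher in these arrays, with a median log2 difference of 0.30 over 68 measured markers.

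Mitotic genes had the lowest median of all lists, −2.62 over 16 of 20 members, and DNA replication genes followed with −2.06 over 17 of 20. Every measured member of both fell, also when adjusted over the list alone. The camera adjusted p was 7.69e-11 for mitotic genes and 3.97e-11 for replication genes, and for both lists the call was lost at adjusted p = 0.244 with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, fell by 3.09 ± 0.17, and the mitotic kinase gene PLK1 fell by 2.98 ± 0.24. MKI67, the gene of the proliferation antigen Ki-67, fell by 1.92 ± 0.27, from 621 to 176. Among replication genes, the helicase subunit gene GINS2 fell by 3.47 ± 0.12, the licensing factor gene CDC6 by 3.38 ± 0.27 and MCM6 by 2.61 ± 0.21. TYMS, which makes thymidylate for DNA, fell by 3.31 ± 0.19. The kinetochore gene SKA3 and the mitotic kinase gene PBK, outside these lists, fell by 3.89 ± 0.23 and 3.37 ± 0.23.

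Among the other large falls, EREG, a ligand of the EGF receptor, fell by 3.76 ± 0.36, from 637 to 46.7, and FOSL1, a subunit of the AP-1 transcription factor, fell by 3.67 ± 0.35. Of 14 immediate early and heat shock genes, 10 fell and 4 did not pass, also when adjusted over the list alone (median −1.40, camera adjusted p = 0.0162). The mean log2 intensity of the list was 8.37, 7.06 and 8.00 in the 2D culture arrays and 6.59, 6.53 and 6.68 in the tumor arrays, so 2D culture replicate 2 lay closest to tumor. The call was lost at adjusted p = 0.383 with an estimated correlation, and with arrays centred on the reference genes 5 fell and 3 rose (median −0.59). The phosphatase gene DUSP1 fell by 2.48 ± 0.37. FOS fell by 2.32 ± 0.57, with a wide spread in 2D culture (292 ± 200, SD, n = 3), and did not pass with an intensity trend and robust prior (adjusted p = 0.0573). In the YAP/TAZ target list, 7 of 10 members fell and 3 did not pass, also when adjusted over the list alone (median −1.03, camera adjusted p = 0.00299, and adjusted p = 0.244 with an estimated correlation). With arrays centred on the reference genes, 3 fell and 2 rose and the median was −0.21. In that list, ANKRD1, a nuclear ankyrin repeat protein, fell by 3.62 ± 0.17, and FJX1 fell by 2.93 ± 0.20.

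Metabolic and stress response lists were lower too. Cholesterol genes had a median of −1.92 (11 of 11 fell, also when adjusted over the list alone; camera adjusted p = 8.35e-08, and adjusted p = 0.244 with an estimated correlation). Besides DHCR7, the sterol sensor gene INSIG1 fell by 2.38 ± 0.16, the sterol carrier gene STARD4 by 2.38 ± 0.15 and HMGCS1, an early enzyme of the pathway, by 2.30 ± 0.17. Of 12 amino acid response genes, 10 fell and 2 did not pass, also when adjusted over the list alone (median −1.04, camera adjusted p = 4.30e-04, and adjusted p = 0.244 with an estimated correlation). With arrays centred on the reference genes, 5 fell and 1 rose, and the median was −0.22. The serine synthesis genes PSAT1, PSPH and PHGDH fell by 3.43 ± 0.15, 1.70 ± 0.22 and 1.69 ± 0.20. Of 8 measured NRF2 target genes, 6 fell, 1 rose and 1 did not pass, also when adjusted over the list alone (median −1.09, camera adjusted p = 0.00733, and adjusted p = 0.244 with an estimated correlation); with that centring 3 fell and 2 rose (median −0.27). HMOX1, the heme oxygenase gene, fell by 2.51 ± 0.12 and SRXN1, a sulfiredoxin gene, by 1.62 ± 0.12, whereas GPX2, a glutathione peroxidase gene, rose by 1.56 ± 0.22. Of 11 p53 target genes, 6 fell, 1 rose and 4 did not pass, also when adjusted over the list alone, with a median of −0.63 that turned to 0.19 with arrays centred on the reference genes. Its camera adjusted p was 0.0497, and adjusted p = 0.244 with an estimated correlation. The call was also lost without 2D culture replicate 1, 2D culture replicate 3 or xenograft tumor replicate 1 (adjusted p = 0.0537, 0.0687 and 0.0586) and with array weights (0.0567). The median lay within the range of random lists of like brightness (−0.86 to 0.14). The apoptosis gene BAX fell by 1.76 ± 0.15 and the cyclin G gene CCNG1 by 1.59 ± 0.14, while TP53INP1, chosen after its values were seen, rose by 0.57 ± 0.20 (adjusted p = 0.0419). That call was lost without 2D culture replicate 1, 2D culture replicate 2, xenograft tumor replicate 2 or xenograft tumor replicate 3 (adjusted p = 0.157, 0.0961, 0.122 and 0.0766).

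Glycolytic enzymes fell in 8 of 9 measured members of 18, also when adjusted over the list alone, with a median of −0.55 that turned to 0.27 with arrays centred on the reference genes and lay within the range of random lists of like brightness (−0.91 to 0.16). After quantile normalization and after cyclic loess normalization, 2 of the 9 fell (medians −0.26 and −0.24). The camera adjusted p was 0.0188, and adjusted p = 0.244 with an estimated correlation. PGAM1 fell by 1.87 ± 0.17, GPI by 0.91 ± 0.12, LDHA by 0.76 ± 0.14 and GAPDH by 0.74 ± 0.13; with the reference centring GPI did not pass (adjusted p = 0.519), and LDHA and GAPDH turned to 0.063 and 0.081. LDHA and GAPDH did not pass after quantile normalization either (adjusted p = 0.0750 and 0.0947). Hypoxia-induced genes, 13 measured of 20, did not pass as a list in camera (median −0.21, adjusted p = 0.319), while fry, which does not compare with other genes, put them downward (adjusted p = 0.00358). Of these, 6 fell, 1 rose and 6 did not pass, or 6, 2 and 5 adjusted over the list alone. The median turned to 0.61 with arrays centred on the reference genes, where 8 rose and 2 fell. STC2, a secreted glycoprotein, fell by 2.08 ± 0.21 and the mitophagy gene BNIP3 by 1.23 ± 0.12, while LOX, a collagen cross-linking enzyme chosen after its values were seen, rose by 0.52 ± 0.14 (adjusted p = 0.0120, and 0.0562 without 2D culture replicate 2). VEGFA, the vascular growth factor, had a log2 difference of −0.13 ± 0.14 and did not pass (adjusted p = 0.481), and had 0.68 with that centring.

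Abundant genes of general function were lower in the deposited values, but the medians of the ribosomal protein, reference and oxidative phosphorylation lists lay within the 95% range of random lists of like brightness (−0.80 to 0.06, −1.04 to 0.15 and −0.82 to 0.29). Of 13 ribosomal protein genes, 11 fell (12 adjusted over the list alone) and 2 did not pass, with a median of −0.45 that turned to 0.37 with arrays centred on the reference genes. Its camera adjusted p was 0.00484, and adjusted p = 0.244 with an estimated correlation. RPL19 fell by 0.92 ± 0.15 and RPL8 by 0.85 ± 0.12, which did not pass with that centring (adjusted p = 0.585 and 0.846). All 7 measured reference genes fell, also when adjusted over the list alone, with a median of −0.71 that became 0.10 once arrays were centred on their mean. That centring removes the mean difference of these genes, so this turn was built in. Their camera adjusted p was 0.00484, and adjusted p = 0.244 with an estimated correlation. Of these, HPRT1, a purine salvage gene, fell by 1.56 ± 0.15 and PPIA, the cyclophilin A gene, by 0.98 ± 0.13, and the latter did not pass with that centring (adjusted p = 0.253). Of 7 nuclear genes of oxidative phosphorylation, 5 fell and 2 did not pass, also when adjusted over the list alone, with a median of −0.62 that turned to 0.20 with arrays centred on the reference genes. The camera adjusted p of that list was 0.0532, and 0.0486 without xenograft tumor replicate 2. COX5A and UQCRC2, subunits of respiratory complexes, fell by 0.91 ± 0.14 and 0.83 ± 0.15, which did not pass with that centring (adjusted p = 0.529 and 0.944). After quantile normalization 5 ribosomal protein, 3 reference and 2 oxidative phosphorylation genes fell.

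Epithelial and mesenchymal genes moved both ways. Of 16 epithelial genes, 3 rose, 4 fell and 9 did not pass, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.338); the median lay above the range of random lists of like brightness (−0.62 to 0.11). The counts were 6 up and 2 down after quantile normalization, and 13 up and 1 down with arrays centred on the reference genes (median 0.99). The tight junction genes CLDN2 and OCLN moved apart: CLDN2 rose by 1.40 ± 0.13 and OCLN fell by 1.54 ± 0.14. DSP, the desmosome gene desmoplakin, rose by 1.32 ± 0.13, and the keratin gene KRT7 fell by 1.17 ± 0.13 (by 0.35 with that centring, adjusted p = 0.0586). Of 12 mesenchymal transition genes, 3 rose, 5 fell and 4 did not pass, also when adjusted over the list alone. The median of that list was −0.17 and its mean −0.06, while camera put it upward (adjusted p = 0.966), so the signs differ, and the median was 0.64 with arrays centred on the reference genes, where 8 rose and 1 fell; after quantile normalization 5 rose and 3 fell. FN1, the matrix protein fibronectin, rose by 2.97 ± 0.15, from 515 to 3989.9, while the receptor kinase gene AXL fell by 1.55 ± 0.20 and the repressor gene SNAI1 fell by 1.21 ± 0.22, which did not pass with that centring (adjusted p = 0.0949). VIM, the intermediate filament vimentin, had a log2 difference of 0.02 ± 0.13 and did not pass (adjusted p = 0.933), but it passed with 0.83 when arrays were centred on the reference genes, 0.42 after quantile normalization and 0.50 after cyclic loess normalization (adjusted p = 3.90e-04, 0.0281 and 0.0125). Of 13 lung epithelial lineage genes, 3 rose (2 adjusted over the list alone), 1 fell and 9 did not pass (median 0.19, camera adjusted p = 0.0866, and 0.0395 with protein-coding genes only); with that centring 12 rose and 0 fell. The transcription factor gene FOXA2 fell by 1.20 ± 0.15, which did not pass with the centring (adjusted p = 0.0700), and the water channel gene AQP5 rose by 0.95 ± 0.12.

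Interferon-stimulated genes did not pass as a list in camera, with 6 of 13 up, 2 down and 5 not passing, also when adjusted over the list alone (median 0.28, camera adjusted p = 0.151). With arrays centred on the reference genes, 11 rose and 1 fell, and after quantile normalization 5 rose and 4 fell. IFITM1, an antiviral membrane protein, rose by 1.72 ± 0.19 and IFI44 by 1.79 ± 0.26 from below the array median, while HERC5, a ligase for ISG15, fell by 1.97 ± 0.19. Of 11 inflammatory genes of the NF-kB list, 3 rose (4 adjusted over the list alone), 2 fell and 6 did not pass (median 0.34, camera adjusted p = 0.151). The median lay above the range of random lists of like brightness (−0.65 to 0.23); the counts were 7 up and 2 down after quantile normalization and 9 up and 1 down with that centring. LIF, a cytokine of the interleukin-6 family, fell by 2.50 ± 0.15 and the adhesion molecule gene ICAM1 rose by 0.77 ± 0.17. Of 9 unfolded protein response genes, 1 rose, 5 fell (7 adjusted over the list alone) and 3 did not pass. The median was −0.31, with a camera adjusted p of 0.270, and turned to 0.08 after quantile normalization and to 0.50 with arrays centred on the reference genes. XBP1, a transcription factor of that response, rose by 1.15 ± 0.15 and DDIT3, a stress-induced transcription factor, fell by 1.41 ± 0.29, which did not pass with that centring (adjusted p = 0.0823). Of 11 stem cell genes, 2 rose (0 adjusted over the list alone), 1 fell and 8 did not pass, with a camera adjusted p of 0.548. The median was 0.04 and the mean −0.10, and fry put the list downward where camera put it upward, so the signs differ; with that centring 9 rose and 1 fell. The gene that fell was MYC, by 2.16 ± 0.16. MHC class I antigen presentation genes had 3 measured members, B2M, TAPBP and ERAP1, and were not tested as a list. No HLA gene was among them. Over all genes tested 1 rose (0 adjusted over the list alone), and their median was 0.26. After quantile normalization, cyclic loess normalization and that centring all 3 rose, with medians of 0.67, 0.76 and 1.08.

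Markers of cells that a mouse could contribute were slightly higher in tumor. Over 68 measured markers the median was 0.30; 25 rose, 4 fell, and 57 had a positive difference. Arrays centred on the reference genes, which raised the median of all genes by 0.82, gave rises in all measured fibroblast, muscle, erythrocyte, keratinocyte, lymphocyte and nerve genes, 12 of 13 endothelial, 9 of 10 adipocyte and 7 of 9 myeloid genes. Of the list of fibroblast and collagen genes, 6 of 20 members were measured, none of them a collagen gene. Of these, 4 rose (5 adjusted over the list alone) and 2 did not pass, with a median of 0.90. The camera adjusted p was 0.0188, and adjusted p = 0.244 with an estimated correlation. DPT, the matrix protein dermatopontin, rose by 2.07 ± 0.40, and LUM, the matrix proteoglycan lumican, by 1.85 ± 0.28 from below the array median. Of 13 endothelial genes, 3 rose, 1 fell and 9 did not pass, also when adjusted over the list alone (median 0.25, camera adjusted p = 0.0215, and adjusted p = 0.248 with an estimated correlation). TIE1, an endothelial receptor gene, rose by 0.70 ± 0.13 from below the array median, and PECAM1 had 0.13 ± 0.14 and did not pass (adjusted p = 0.465), but passed with that centring (0.95, adjusted p = 3.55e-04). Of 10 adipocyte genes, 4 rose, 1 fell and 5 did not pass, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.0334, and adjusted p = 0.244 with an estimated correlation). Without xenograft tumor replicate 1 the adjusted p was 0.0530. The endothelial and adipocyte lists also lost their camera calls with arrays centred on the reference genes (adjusted p = 0.103 and 0.225). After quantile normalization both calls were lost too (0.229 and 0.173), with medians of 0.12 and 0.22. In the adipocyte list CFD, the complement factor D gene, rose by 1.42 ± 0.20. PPARG, a nuclear receptor of fat cells, fell by 0.91 ± 0.14, which did not pass with the reference centring (adjusted p = 0.588). Of 9 myeloid genes, 3 rose (4 adjusted over the list alone), 1 fell and 5 did not pass (median 0.28, camera adjusted p = 0.0544, and 0.0356 without xenograft tumor replicate 3). The protease gene CTSS rose by 1.81 ± 0.12 and the lipopolysaccharide receptor gene CD14 fell by 1.71 ± 0.21. In 2D culture, which holds no mouse cells, CTSS and CD14 had intensities of 150 and 77.6, and CFD and PPARG 93.3 and 109. These lie above the array medians, so changes of these genes cannot be assigned to host cells. The same holds for DPT, TTN and EPB42, at 21.2, 15.5 and 13.7 in 2D culture. LUM, TIE1, KRT1, S100B and NCAM1 lay below the array medians there. Of 7 skeletal muscle genes, 5 rose and 2 did not pass, with 1 fall adjusted over the list alone (median 0.54, camera adjusted p = 0.0532, and 0.0333 without xenograft tumor replicate 3 and 0.0400 with the mean of a gene's probe sets), and TTN, the titin gene, rose by 1.26 ± 0.14. Of 5 lymphocyte genes, 3 rose (4 adjusted over the list alone) and 2 did not pass (median 0.43, camera adjusted p = 0.0532). The camera adjusted p was 0.0475, 0.0446 and 0.0421 without 2D culture replicate 1, xenograft tumor replicate 2 or xenograft tumor replicate 3. NKG7, a gene of cytotoxic granules, rose by 0.61 ± 0.12. In 2D culture 0 of these 5 genes lay below the array median, so their rises cannot be assigned to host cells. Of 6 nerve genes, 2 rose, S100B by 0.80 ± 0.16 and NCAM1 by 0.66 ± 0.17, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.102). Of 10 keratinocyte genes, 1 rose and 1 fell (0 adjusted over the list alone), and the keratin gene KRT1 rose by 0.56 ± 0.13 from below the array median (median 0.16, camera adjusted p = 0.158). The 2 measured erythrocyte genes did not pass, also when adjusted over the list alone, and had a median of 0.29; the larger difference was that of EPB42, with 0.35 ± 0.14, which became 1.17 and passed with that centring (adjusted p = 1.21e-04).

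**Figure D2:**
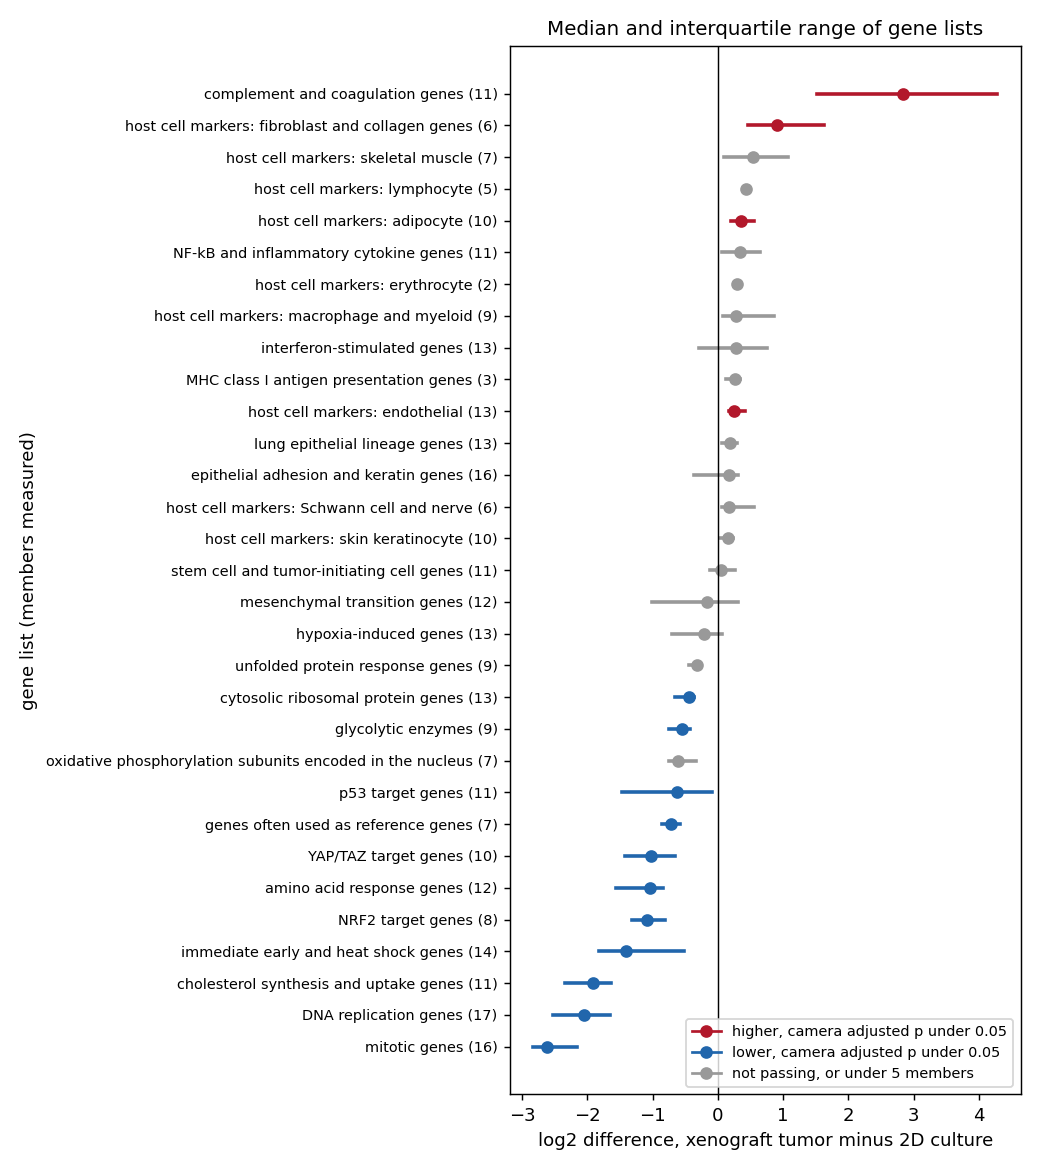
Log2 difference, tumor minus 2D culture, of the 31 gene lists with the number of measured members in parentheses. Points are medians and lines interquartile ranges over members. Red and blue mark lists higher and lower at a camera adjusted p under 0.05 with the preset correlation, and grey marks the others. Mitotic genes lie lowest at −2.62 and complement and coagulation genes highest at 2.84. The medians of the glycolytic, p53 target, ribosomal protein, reference, hypoxia, mesenchymal, unfolded protein response and oxidative phosphorylation lists turn above 0 with arrays centred on the reference genes. That centring adds 0.82 to every difference, and for the reference list the turn is built in.

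Over all 14884 genes, limma called 6760 changed at an adjusted p under 0.05, of which 2375 were higher and 4385 lower in tumor, so 64.9% were lower. At least 2-fold, 438 genes were higher and 1496 lower. The 3 values of tumor lay entirely to 1 side of those of 2D culture in 55.4% of genes, against 10% by chance. The difference followed brightness. The 4384 genes with a mean log2 intensity of 6 or more had a median of −0.50, which turned to 0.32 with arrays centred on the reference genes, and the 7704 under 5 had a median of 0.12. Of 29 lists tested, 4 were called higher and 11 lower, and 0 of these 15 calls held with an estimated correlation. That setting estimates the correlation from 6 arrays and called no list. Its lowest unadjusted p in camera was 0.0310, for complement and coagulation genes. Mitotic and adipocyte genes had the same adjusted p of 0.244, so a call lost there says little about a list.

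**Figure D3:**
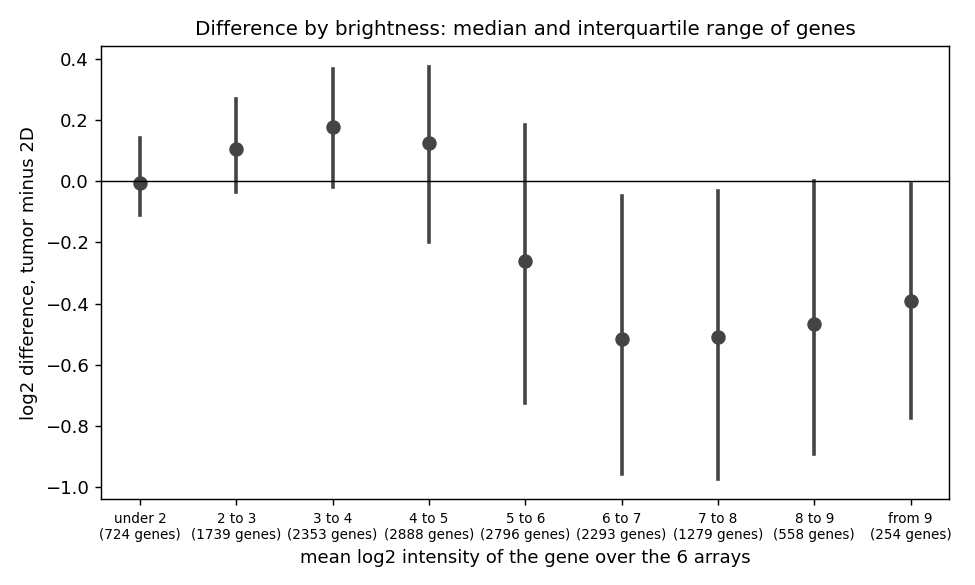
Log2 difference, tumor minus 2D culture, against the mean log2 intensity of a gene over the 6 arrays. Points are medians and lines interquartile ranges over the genes of a class; from 6 to 7 the median is −0.51 and from 3 to 4 it is 0.18, in the values as deposited; centring on the reference genes turns the median of genes at 6 or more to 0.32.

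The split by direction rests on the scaling. Quantile normalization gave 2801 genes higher and 2914 lower, and cyclic loess normalization (chosen after seeing the data) 2938 and 2935. Both were run on named probe sets or genes only and make their distributions alike between arrays. A near even split was thus largely built in and cannot tell which split is right. Centring on the reference genes, which raised the median of all genes by 0.82, gave 10905 and 1036. Apart from the estimated correlation, the calls of the mitotic, replication, cholesterol and complement lists held under each of these scalings. They also held with dim genes left out at a mean log2 of 5 or 6. The amino acid, NRF2, YAP/TAZ and immediate early lists lost theirs with dim genes left out. Their medians (−1.04, −1.09, −1.03 and −1.40) did lie below the ranges of random lists of like brightness. Those ranges were −0.86 to 0.06, −0.90 to 0.16, −0.83 to 0.15 and −0.81 to 0.02. Under cyclic loess normalization the glycolytic, fibroblast, endothelial, adipocyte, p53, ribosomal protein and reference gene lists lost theirs. There the median of the fibroblast list was 1.06 (camera adjusted p = 0.0501), and those of the glycolytic and ribosomal protein lists were −0.24 and −0.07. The glycolytic, p53, ribosomal protein and reference gene lists also lost their calls with dim genes left out and after quantile normalization. At a mean log2 of 5 or more the p53, ribosomal protein and reference gene lists had a camera adjusted p of 0.540, 0.178 and 0.123.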

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

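The comparisons of unnamed probe sets and with matched random lists and the tests of dilution and of liver RNA as a whole cause below were chosen after the results they bear on had been seen.

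Probe sets without a gene name were left out of the comparison above, and a signal was looked for in them because they are data that no comparison used. Of 37519 such probe sets, limma called 4283 higher and 3318 lower in tumor at an adjusted p under 0.05, and 1585 were at least 2-fold higher and 1415 at least 2-fold lower. What these probe sets measure was not analysed here.

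The rise of complement and coagulation genes (median log2 difference 2.84) was weighed against liver RNA and an acute phase response. An added list of abundant hepatocyte genes had a median of 0.42, with 10 of 19 members up, and its upper quartile lay below the lower quartile of the complement and coagulation list (difference −0.95). ALB, the albumin gene chosen after its values were seen, stayed dim, at 4.22 in 2D culture and 6.19 in tumor. The test of liver RNA set beforehand did not decide. The quartile gap argues against liver RNA as the whole cause only if human probes read mouse transcripts of both lists alike, which was not tested. A small contribution cannot be told apart from other host RNA. An acute phase response of the tumor cells stays open too: the added list of such genes had a median of 0.039, a mean of −0.01 and members going both ways (4 up, 4 down), and growth in a mouse itself may be a biological source that the design names and no test separated.

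The fall of mitotic and DNA replication genes was weighed against dilution of A549 RNA by RNA of mouse cells. Dilution would lower all genes of the tumor cells by a like amount, if mouse RNA adds no signal of its own. The 33 genes of the 2 lists had a median of −2.31, against −0.57 in 27 reference, ribosomal protein and oxidative phosphorylation genes. The difference was −1.75, and the upper quartile of the former (−1.92) lay below the lower quartile of the latter (−0.76). The values argue against dilution as the whole cause only under that condition. Mouse cells also express the comparison genes, and human probes could read some of that RNA, so the gap alone cannot decide. A smaller share of dividing cells in the tumors is a candidate explanation that stays open; the histone genes meant to test it had 0 named probe sets, so that test could not be run.

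Lower signals of bright genes and slightly higher host markers were weighed together. Dilution by host RNA remains open for the bright genes: the medians of the reference, ribosomal protein and oxidative phosphorylation lists (at or below −0.45) only restate that bright genes fell, and the 3 tumor arrays, with reference gene means of 7.39, 7.65 and 7.55 and host marker means of 4.49, 4.42 and 4.39 on the log2 scale, are too few to decide, although the array with the lowest reference mean had the highest host mean, as dilution would give; the other 2 arrays did not follow that order. Mouse RNA read by the human probes may also account for the host markers: their median of 0.30 lay above the range of matched random lists (−0.01 to 0.19), as did the fibroblast, adipocyte and muscle lists by themselves. The other 6 lists, endothelial (0.25 in −0.07 to 0.33) and myeloid (0.28 in −0.44 to 0.35) among them, lay inside their ranges, and the myeloid list missed the threshold that all of 3 main host lists had to pass (adjusted p = 0.0544, 0.0356 without xenograft tumor replicate 3 and 0.0331 with protein-coding genes only). The submitters' normalization is a further open explanation. Quantile normalization of the named probe sets brought the median of bright genes from −0.50 to −0.06. It makes the quantiles of the arrays equal whatever made them differ, so this cannot decide between explanations. Growth in a mouse as a biological explanation was not tested.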

How the results depend on the processing

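Of the alternatives, cyclic loess normalization and protein-coding genes only were chosen after seeing the data, and the cause of a change was not tested unless given. Over these settings, the genes named in the report kept their side of the threshold in 1420 comparisons, fell short in 21, newly passed in 5 and reversed in 3. List tests kept theirs in 499, fell short in 56 and newly passed in 21. A change of direction counted as reversed only where either fit passed. VIM, for example, reached −0.25 without passing. Leaving out 1 array gave 5748 to 6734 changed genes. The replicate numbers did not pair the samples (correlations of deviations 0.03, 0.01 and −0.03), and with the replicate block 6601 genes were changed, 6408 of them as in the main result, and the skeletal muscle list newly passed (adjusted p = 0.0359). Quantile normalization gave 2914 genes lower and, at least 2-fold, 704 higher and 775 lower, and the adjusted p of the glycolytic list rose to 0.153. With arrays centred on the reference genes, 11941 genes were changed (10905 higher, 1036 lower), 4882 at least 2-fold (4623 higher, 259 lower), and the glycolytic and fibroblast lists had an adjusted p of 0.114 and 0.214, although the fibroblast median rose to 1.72 with 6 of 6 up; by construction this centring adds the fall of the reference genes to every gene. Cyclic loess normalization gave 718 and 719 genes at least 2-fold higher and lower, with 0.175 for glycolysis and 0.0501 for fibroblast genes. Filters leave fewer genes to test: a mean log2 of 5 or more gave 1072 genes higher, 265 at least 2-fold, and 0.153 for glycolysis; 6 or more gave 3333 changed (605 higher, 2728 lower), 1129 at least 2-fold (174 higher, 955 lower) and 0.224 for glycolysis; protein-coding genes only gave 264 at least 2-fold higher, and the myeloid, muscle, lymphocyte and lung lists newly passed (adjusted p = 0.0331, 0.0331, 0.0335 and 0.0395) while the p53 list lost its call (0.0841); a threshold of 0.01 gave 1368 higher. With an estimated correlation the glycolytic, mitotic, replication and fibroblast lists had an adjusted p of 0.244, and with fry, which tests a list by itself, hypoxia genes had 0.00358 and the myeloid, muscle, keratinocyte, lymphocyte, nerve, unfolded protein response and oxidative phosphorylation lists newly passed as well (0.00514, 0.00495, 0.0183, 0.0183, 0.00528, 0.00951 and 4.40e-04). Centring on the reference genes turned the medians of glycolytic, p53 target, ribosomal protein and reference genes to 0.27, 0.19, 0.37 and 0.10, LDHA to 0.063, GAPDH to 0.081 and VEGFA to 0.68. The setting that keeps probe sets with several symbols gave no values, because there were 0 of them. How far signals lie above background is not known from the table, which limits what dim genes can show.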

Other observations

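The comparison of RNA classes, also with random lists, was chosen after its result was seen, and the tests of added gene lists after the leading genes, but before the values of these lists, had been seen.

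Genes of microRNAs were more often higher than lower in tumor. Of 1072 such genes, 365 rose and 34 fell, with a median log2 difference of 0.19 against 0.03 in random lists of like brightness (95% range 0.01 to 0.05). The median was 0.16 after quantile normalization and 0.14 after cyclic loess normalization, and centring arrays on the reference genes gave 1015 up and 2 down. Of 1398 long noncoding RNA genes, 231 rose and 126 fell, with a median of 0.12, inside the range of random lists of like brightness (0.086 to 0.124), that was 0.03 after quantile normalization and 0.93 with that centring. Of 11916 protein-coding genes, 1672 rose and 4164 fell. The counts were 2200 and 2696 after quantile normalization and 8177 and 1003 with arrays centred on the reference genes. The median of protein-coding genes, −0.105, lay below the range of random lists of like brightness (−0.093 to −0.068). The 498 remaining genes had a median of 0.12, above their range (0.012 to 0.085).

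Hepatocyte genes rose in 10 of 19 measured members, also when adjusted over the list alone (median 0.42, camera adjusted p = 0.00138, and adjusted p = 0.466 with an estimated correlation). The largest rise was that of APOH, an apolipoprotein of plasma chosen after its values were seen, by 1.84 ± 0.19, from 115 to 418. The median was 0.29 after quantile normalization and 1.24 with arrays centred on the reference genes. Of 13 acute phase genes, 4 rose, 4 fell and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 0.535).

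A hypothesis was that low EREG, FOSL1 and DUSP5 (the last chosen after its values were seen; it fell by 2.98 ± 0.31) may go with lower output of the ERK pathway. In a list of other ERK output genes, 7 of 13 fell (8 adjusted over the list alone), 1 rose and 5 did not pass, with a median of −0.59 and a camera adjusted p of 0.142. The median turned to 0.23 with arrays centred on the reference genes, so the test leaves the hypothesis open. Another hypothesis, that lysosomal genes could rise where growth genes fall, met a median of −0.35 in 16 genes, with 1 up and 8 down, also when adjusted over the list alone (camera adjusted p = 0.193). The bound set beforehand, a median at or below 0, was met but takes no account of the general fall of bright genes: the median was 0.47 with arrays centred on the reference genes and 0.03 after quantile normalization, so this too stays open.

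Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real split, gave as many as 6760 changed genes in limma, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05. Each of the other splits mixes tumor and 2D culture arrays, so the group difference enters its residual spread and keeps its count low. The count of 0 is thus no chance level to set against 6760.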
